A study of Caenorhabditis elegans with 4 samples.

How the data were processed

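The series measured where the protein MAU-2 sits on the genome of wild-type Caenorhabditis elegans embryos of mixed stages, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels' protocols, embryos were obtained by bleaching gravid adults grown in liquid culture, cross-linked alive with formaldehyde and sonicated. MAU-2 was precipitated with an affinity-purified rabbit polyclonal antibody, and part of each extract was kept as input. The series holds 4 samples, namely 2 ChIP replicates and 2 input replicates. Peak lists of both ChIP replicates and 1 list for the whole series, called the series-wide list below, were used. Files of the input samples were not analysed here.

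Reads were aligned with BWA to ce10, per the submitters' processing notes, which give no version. The file headers name WormBase WS220 as the build, and all coordinates are given on it, counted from 1. Per the file headers and columns, the replicate lists came from MACS with no version and the series-wide list came from MACS v2. How the input was used, the thresholds, and whether the reads of the replicates were pooled for the series-wide list are not given in the sources used here. Each peak carries a score that the authors' peak caller assigned, and the deposited files do not name its scale. The scores ran from 50.04 to 3166.99 in replicate 1 and from 50.16 to 3225.28 in replicate 2, with 42 and 12 peaks at exactly 3100, whereas in the series-wide list they ran from 1.31 to 120.66. The scores of the 2 kinds of list are therefore on different scales. Within a list they were used only to describe, rank or filter peaks and to compare X with autosomal peaks. For the replicates they were also used to correlate ranks. The lists give no read numbers, so sequencing depth is unknown, and no binding level could be compared between samples.

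The main comparisons and their tests were fixed before the data were examined. Tests of single autosomes, of end regions by chromosome, and of X peak scores and widths were not in that plan. Nor were those of wide peaks and dense stretches. Peaks of 2 lists were called overlapping when they shared at least 1 bp. The significance of overlap was set by placing each peak of one list at random on its own chromosome 10000 times (one-sided permutation test, smallest possible p = 0.0001). The number of peaks on X was tested against the X share of the nuclear genome length with a two-sided exact binomial test. The share of autosomal peaks in the end regions (the first and the last 33.3% of each chromosome's length) and the median distance between neighbouring peak midpoints were tested with 10000 random placements (two-sided permutation tests, smallest possible p = 0.0002). Scores of overlapping peaks were compared by Spearman's rho with 100000 random pairings. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. They treat peaks as independent, which peaks lying close together are not. The highest coordinate in the series-wide list served as the length of each chromosome, since no separate table of lengths of this build was used here. Chromosome shares, end regions and right ends rest on this choice. Mitochondrial peaks were left out of the chromosome tests. Adjusted p-values are by Benjamini-Hochberg over the 6 chromosomes of a list unless stated otherwise. Peaks named in the text are the 20 with the highest score in the series-wide list among those that overlap a peak in both replicate lists, and the highest of each chromosome. Any other peak or region named was chosen after its values were seen.

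Alternatives were other overlap rules, each replicate list alone, the higher-scoring 50% of a list, equal peak numbers, only peaks present in both replicate lists, end regions of 25%, and covered bases in place of peak numbers. Merging peaks within 1000 bp, leaving out wide and chromosome-end peaks, leaving out the densest 100 kb of each chromosome or the densest 1 Mb of X or of every chromosome, leaving out the 2 stretches with most peaks in neither replicate list, comparing wide peaks within the highest score quartile or with a reciprocal overlap, shifting peaks by up to 100 kb, and leaving out scores of 3100 or more were chosen after seeing the data. The tests were checked on simulated data. Among 40 pairs of randomly placed lists of the replicate sizes, 0 passed the threshold of 0.05 for overlap. Among 40 random series-wide lists, 2 passed for the X share, 2 for the end regions and 0 for spacing. The random lists placed peaks independently, as the tests themselves assume. These rates therefore do not show how the tests behave when peaks lie close together. A simulated replicate 2 list of 762 peaks with 60% of its peaks copied from replicate 1 gave an overlap of 60.9%. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

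Planned tests of transcription start sites, tRNA genes, gene feature classes, 15 gene lists (among them cell type markers), base composition and the X share of genes were not run, because the gene table used here is on another assembly (WBcel235) and coordinates were not moved between builds. Peaks are therefore reported by position, without genes.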

Results

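MAU-2 is the C. elegans member of the protein family that, with its partner SCC-2, loads cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops. Its binding sites were mapped in mixed-stage wild-type embryos as 2 ChIP-seq replicates, with 2 input samples whose files were not analysed here. The labels do not say whether the replicates came from separate cultures. The list of replicate 1 held 1880 peaks with a median width of 330.5 bp, covering 1.00% of the nuclear genome. The list of replicate 2 held 762 peaks with a median width of 464 bp, covering 0.604%. The series-wide list held 1018 peaks with a median width of 303.5 bp, covering 0.537%. Replicate 1 thus had 2.47 times as many peaks as replicate 2, and 1.66 times the covered bases. Sequencing depth is unknown from these files, so this difference in number could not be set against depth.

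The first comparison asked how far the replicates found the same MAU-2 sites. Most replicate 2 sites were also found in replicate 1, whereas replicate 1 held a large set of low-scoring sites of its own. Of the 762 replicate 2 peaks, 633 overlapped a replicate 1 peak, which is 83.1% (95% interval 80.2 to 85.7). Random placement gave 2.18% on average and 4.46% at most (one-sided permutation p = 0.0001, the smallest the test can give). In the other direction, 690 of the 1880 replicate 1 peaks overlapped a replicate 2 peak, or 36.7% (34.5 to 38.9), against 0.971% at random (permutation p = 0.0001). When replicate 1 was reduced to its 762 highest-scoring peaks, this share was 68.4%. Matched peaks lay close together, with a median of 34 bp between midpoints over 633 pairs. Their scores correlated across peaks with Spearman's rho = 0.72 (permutation p = 1e-05, the smallest it can give), where peaks are not independent replicates.

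Sharing between replicates rose with peak score. In the lowest score quartile of replicate 1, 11.3% of 470 peaks (8.56 to 14.5) were found in replicate 2, and in the highest quartile 86.8% (83.4 to 89.7) were. In replicate 2 the share found in replicate 1 went from 68.1% (60.9 to 74.6) in the lowest quartile to 96.8% (93.3 to 98.8) in the highest. In both directions the intervals of the lowest and highest quartiles did not overlap. The replicate 1 peaks without a counterpart had a median score of 87.6, against 342 for those with one. Of those without a counterpart, 10.6% lay within 1000 bp of a replicate 2 peak.

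**Figure D1:**
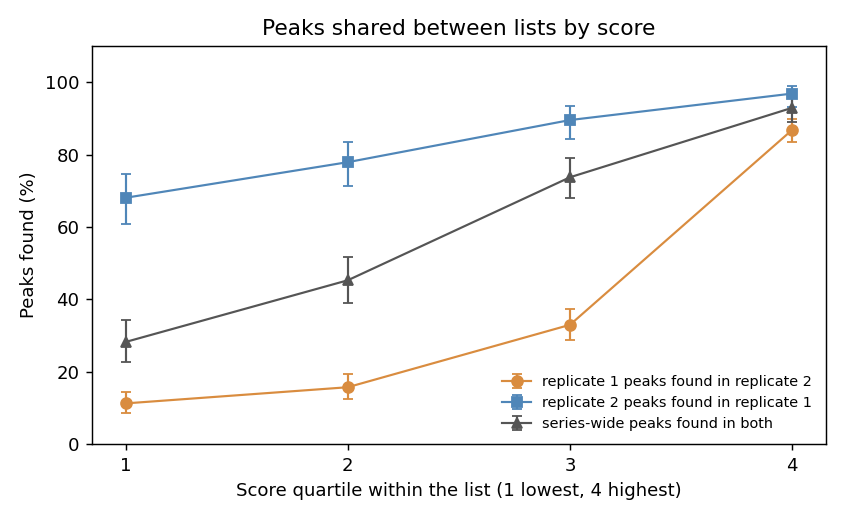
Percentage of peaks found in the other list (y axis) by score quartile within each list (x axis, 1 lowest and 4 highest); points are shares and bars are 95% Clopper-Pearson intervals. The share of replicate 1 peaks found in replicate 2 goes from 11.3% to 86.8%, and that of replicate 2 peaks found in replicate 1 from 68.1% to 96.8%.

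Most peaks of the series-wide list were present in both replicates. Of the 1018 peaks, 611 (60.02%, 56.9 to 63.0) overlapped a peak in both replicate lists, 138 in replicate 1 only, 105 in replicate 2 only and 164 in neither. The peaks in both lists had a median score of 14.2 and a median width of 355 bp, against 4.08 and 204.5 bp for the peaks in neither list. The share in both lists was 28.2% (22.8 to 34.2) in the lowest score quartile and 92.9% (89.03 to 95.7) in the highest. Requiring a reciprocal overlap of at least 50% lowered the share in both lists from 60.02% to 33.99%.

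The 20 highest-scoring sites found in both replicates included sharp peaks and very wide regions. On the chromosomes, 4 lay on I, 4 on II, 3 on III, 1 on IV, 3 on V and 5 on X. Of the 20, 13 were between 403 and 749 bp wide, and 5 were wider than 2000 bp. The highest-scoring site lay on chromosome II from 5844629 to 5845210, with a score of 120.66 in the series-wide list, 2624 in replicate 1 and 1568 in replicate 2. The highest site of chromosome I, from 4172038 to 4172577, scored 114.69. That of X, from 13306782 to 13307340, scored 99.03, and a further X site from 13665274 to 13665740 scored 83.62. Chromosome II held 3 more sites of this kind, from 5543423 to 5543980 with a score of 90.29, from 5104941 to 5105404 with 78.70 and from 7200046 to 7200521 with 76.88. The highest site of chromosome IV, from 8375264 to 8375711, scored 89.84, and that of III, from 10989368 to 10989951, scored 64.91. All 20 had a score of at least 1095 in replicate 1 and at least 497 in replicate 2, against list medians of 118 and 135.

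The widest region of the series-wide list lay near the last listed position of chromosome I, from 15060218 to 15071382, and was 11165 bp wide. The right end of this chromosome carries the array of large ribosomal RNA genes in this species. Input files were not analysed here, so MAU-2 binding in this region cannot be told from signal also present in input. The region was 11077 bp wide in replicate 1 and 11157 bp wide in replicate 2, with a score of 3100 in both. The highest-scoring site of chromosome V was a region of 6712 bp from 17119911 to 17126622, followed by one of 4029 bp from 17128110 to 17132138, both with a score of 3100 in each replicate. On X, a region of 4845 bp from 109455 to 114299 also had a score of 3100 in each replicate. Exactly this score was shared by 42 peaks of replicate 1 and 12 of replicate 2, so equal scores of 3100 do not show equal signal. Other wide regions were in 1 replicate list only. A region of 8055 bp on V, from 7916913 to 7924967, was absent from replicate 1. Regions of 7078 bp on I, from 10212200 to 10219277, and of 5073 bp on IV, from 11070827 to 11075899, were absent from replicate 2. In the nuclear genome, 48 series-wide peaks were wider than 2000 bp. Of these, 42 (87.5%, 74.8 to 95.3) were present in both replicate lists, compared with 59.0% of the other 964 nuclear peaks (Fisher's exact test, two-sided, p = 5.4e-05). This comparison was not planned. Within the highest score quartile no such difference was detected, with 39 of 42 (92.9%) against 197 of 208 (94.7%) in both lists (Fisher's exact p = 0.71). With the mitochondrial ones, peaks wider than 2000 bp made up 33.7% of all covered bases.

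A further comparison set the X chromosome against the autosomes. In C. elegans the X of hermaphrodites is the target of the dosage compensation complex, which contains a condensin, a relative of cohesin. MAU-2 peaks were denser on X than on the autosomes in all 3 lists. The series-wide list held 11.96 peaks per Mb on X and 9.69 per Mb on autosomes, a ratio of 1.23. The ratio was 1.33 in replicate 1 and 1.23 in replicate 2. X carried 212 of the 1012 nuclear series-wide peaks, or 20.9% (18.5 to 23.6), against 17.7% of the genome length (exact binomial test, two-sided, p = 0.0074, adjusted p = 0.028). In replicate 1 X carried 22.2% (20.4 to 24.2) of 1879 peaks (exact binomial p = 4.3e-07, adjusted p = 2.6e-06). In replicate 2 it carried 20.9% (18.03 to 23.9) of 762 peaks (exact binomial p = 0.023), which did not pass the adjustment (adjusted p = 0.14). The series-wide list belongs to the same series and has no sample of its own, so its value is not independent of the replicates. Among the 611 peaks in both replicate lists the X share was 22.4% (19.2 to 25.9, exact binomial p = 0.0029). Counted in covered bases, of which a few wide peaks take a large part, X held 20.4% and the difference was not significant (permutation p = 0.25).

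Among the autosomes, the series-wide list had a lower density on chromosome I, at 8.16 peaks per Mb (12.2% of peaks against 15.0% of length, exact binomial test, adjusted p = 0.028), which did not pass in replicate 1 (adjusted p = 0.61) or replicate 2 (adjusted p = 0.43). Chromosome V had fewer peaks than its length predicts in replicate 1, with 17.5% of peaks against 20.9% of length (exact binomial test, adjusted p = 0.00066), while replicate 2 gave 18.5% (adjusted p = 0.36) and the series-wide list 19.3% (adjusted p = 0.24). Chromosomes II, III and IV did not pass the adjusted threshold in any of the 3 lists. X peaks had a higher median score than autosomal peaks in the series-wide list, at 11.9 against 7.95 (permutation p = 0.0002, adjusted p = 0.0006 over 6 such comparisons). The densest 100 kb of II, III and IV, with 18, 29 and 29 peaks, had median scores of 4.82, 4.04 and 3.83. That of I had 13.8, that of V 4.89 and that of X 5.2. The test treated such neighbouring peaks as independent, and medians without these stretches are not given here. The permutation test did not pass in replicate 1, with 108.1 against 120.7 (adjusted p = 0.17), or in replicate 2, with 162 against 130 (adjusted p = 0.17). Median widths on X and autosomes were 303 and 302 bp in the series-wide list (permutation test, adjusted p = 0.93). In replicate 1 X peaks were narrower, at 274 against 344 bp (permutation test, adjusted p = 0.0006), which did not pass in replicate 2, at 435 against 466 bp (adjusted p = 0.38).

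**Figure D2:**
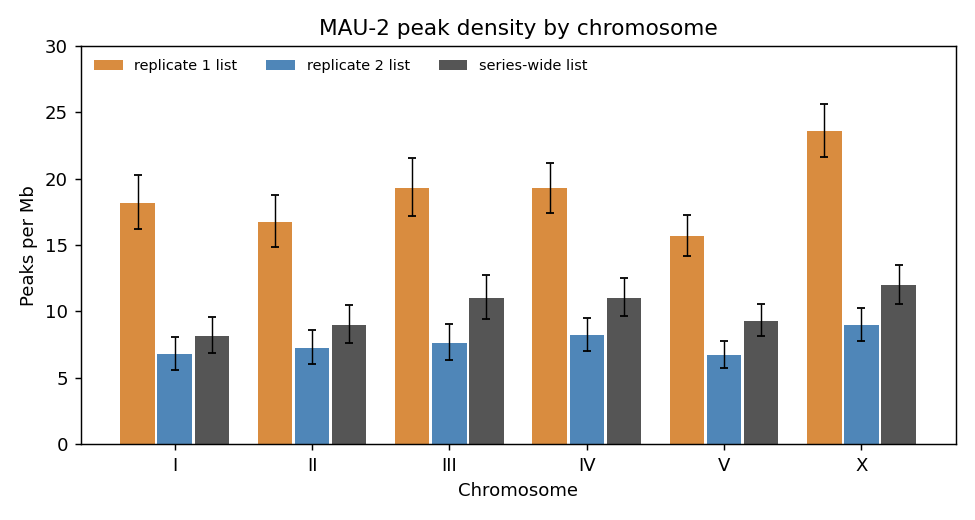
Peaks per Mb (y axis) on each nuclear chromosome (x axis) in the replicate 1, replicate 2 and series-wide lists; bars are the densities and error bars are 95% Clopper-Pearson intervals of the chromosome's share of peaks. X has the highest density in each list, at 23.6, 8.97 and 12.0 peaks per Mb.

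Another comparison set the arms of the autosomes, which are richer in repeats, against their gene-dense centres. Across the 5 autosomes, 497 of 800 series-wide peaks (62.1%, 58.7 to 65.5) lay in the end regions (the first and last 33.3% of each chromosome), below the 66.7% of random placement (permutation p = 0.008). Neither replicate list showed this difference, with 68.2% in replicate 1 (permutation p = 0.21) and 66.0% in replicate 2 (p = 0.75). Leaving out the densest 100 kb of each chromosome turned the series-wide value to 67.5% (permutation p = 0.67), and merging peaks within 1000 bp gave 64.2% (p = 0.23). The chromosomes differed in direction. In the series-wide list the end regions held fewer peaks on IV (52.8%, permutation test, adjusted p = 0.0012) and II (56.9%, adjusted p = 0.044) and more on I (78.0%, adjusted p = 0.021). In replicate 1 they held more on I (79.2%, permutation test, adjusted p = 0.0006) and, opposite to the series-wide list, on II (74.2%, adjusted p = 0.03), and fewer on III (53.0%, adjusted p = 0.0006). In replicate 2 no chromosome passed the adjustment, the lowest p being that of I with 78.4% (permutation p = 0.016, adjusted p = 0.096). The permutation tests placed peaks independently, which peaks of 1 dense stretch are not. Of the 193 series-wide peaks on IV, 29 lay in its densest 100 kb, within the central 33.3%. On II the densest 100 kb, likewise central, held 18 of 137. That of III, also central, held 49 of the 266 replicate 1 peaks there. The lower shares on these chromosomes rest partly on such stretches, and shares without them are not given here by chromosome. On X, 66.5% of the series-wide peaks lay in the end regions (permutation test, adjusted p = 1), and the interval of 59.7 to 72.8% includes the value of random placement.

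The last comparison concerned spacing. MAU-2 peaks were grouped along the chromosomes more closely than random placement gives. The median distance between neighbouring series-wide peaks was 35.1 kb, compared with 67.7 kb at random (central 95% range 63.4 to 72.2, permutation p = 0.0002, the smallest the test can give). Replicate 1 gave 21.8 kb against 36.5 kb, and replicate 2 gave 67.1 kb against 90.3 kb, each with a permutation p = 0.0002. Of the gaps between neighbours, 35.7% were under 5 kb, against 5.00% expected. Merging peaks within 1000 bp reduced the 1012 nuclear peaks to 732 regions, and the median distance was then 86.5 kb against 93.0 kb (permutation p = 0.07).

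The densest 100 kb stretches were on III and IV, with 29 series-wide peaks each, where 1000 random placements gave at most 10. On III, from 7406441 to 7448136, 13 of the 29 peaks were present in both replicate lists and 5 in neither. On IV, from 6647002 to 6730864, 0 were in both and 25 in neither, and the median score was 3.83. On II, 18 peaks lay from 9774551 to 9824204, of which 1 was in both lists and 17 in neither. The densest stretch of X held 10 peaks from 5022636 to 5085822, of which 3 were in both lists, and the highest number at random was also 10.

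**Figure D3:**
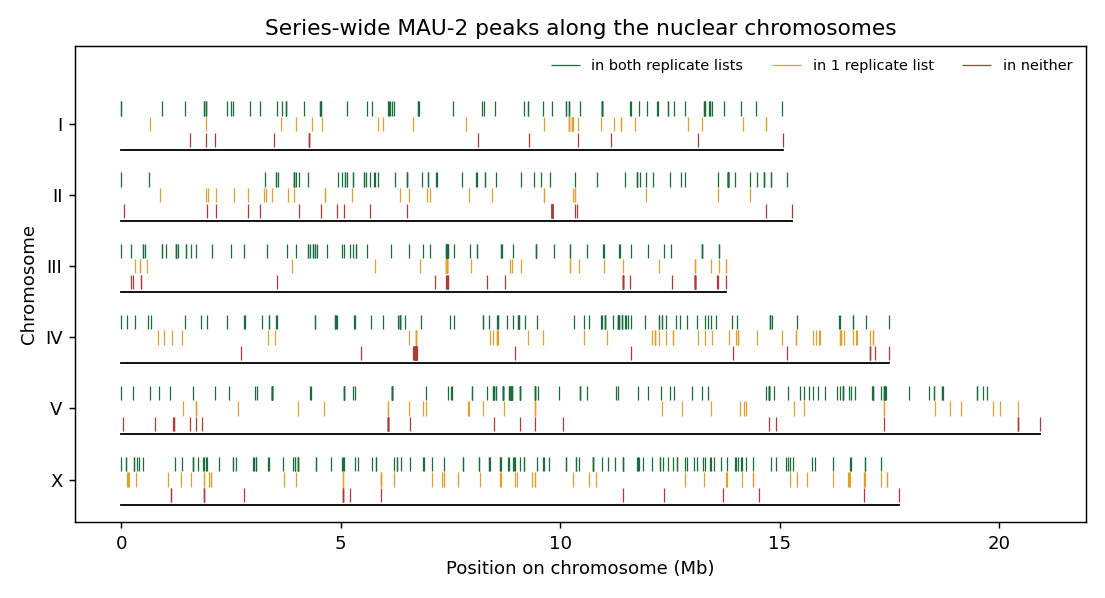
Position in Mb (x axis) of the nuclear peaks of the series-wide list on each chromosome (y axis); each tick is 1 peak midpoint, in 3 rows for peaks in both replicate lists, in 1 list and in neither. The peaks in neither list pile up on IV near its 25 such peaks between 6647002 and 6730864 and on II between 9774551 and 9824204.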

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

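The series-wide list held 6 peaks on mitochondrial DNA, a part of the data that the comparisons between chromosomes do not use. They ran from position 61 to 12890, covered 11517 bp and scored between 13.95 and 31.37, the highest being the one from 4291 to 6592. The list of replicate 1 held 1 mitochondrial peak, from 7675 to 9654 with a score of 66.8, and that of replicate 2 held 0. The input samples, against which this signal would have to be judged, were not analysed here.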

How the results depend on the processing

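The overlap of the replicates and the correlation of their scores kept their direction and their side of the threshold under each alternative tried for them. The X share kept its direction but did not pass the threshold when counted in covered bases (20.4%, permutation p = 0.25), without the densest 1 Mb of X (19.1% against 16.8% of the remaining length, exact binomial p = 0.061) or, after adjustment over the chromosomes, in replicate 2 (adjusted p = 0.14). Over the overlap rules and reduced lists, the share of replicate 2 peaks found in replicate 1 ranged from 67.3% to 89.2% and that of replicate 1 peaks found in replicate 2 from 27.7% to 68.4%. The X share ranged from 19.1%, without the densest 1 Mb of X, to 25.05% in the higher-scoring 50% of peaks. The share of series-wide peaks in both replicate lists moved from 60.02% to 33.99% with a reciprocal overlap of at least 50%, where the cause was not tested. The share of autosomal peaks in the end regions was the result least able to bear a change of setting. It was 68.2% in the replicate 1 list alone and 66.0% in the replicate 2 list alone. In the series-wide list it was 62.1% in the higher-scoring 50% with a permutation p of 0.071 and 64.2% with peaks within 1000 bp merged. Without the densest 100 kb of each chromosome it was 67.5%, so its direction depended on those stretches. It remained significant at 60.5% among peaks in both replicate lists and at 61.0% without wide and end peaks, and end regions of 25% gave 43.4%, where random placement gives 49.98%. The median spacing lost significance only with peaks within 1000 bp merged (86.5 kb, permutation p = 0.07). No paired analysis was possible because the replicate numbers are shared only with input samples, whose files were not analysed here. The higher share of wide peaks in both replicate lists held with a reciprocal overlap of at least 50% (36 of 48 against 32.2% of the others, Fisher's exact p = 4.9e-09) but not within the highest score quartile (92.9% against 94.7%, Fisher's exact p = 0.71), and the cause was not tested. The lists hold no read numbers, so depth and its limits are unknown. Planned tests of start sites, tRNA genes, gene classes, gene lists, base composition and the X share of genes were not run.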

Other observations

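The tests of the last peaks of the chromosomes, of peaks absent from both replicate lists, of X against autosome centres, of short gaps after merging, of the number of peaks in the densest 1 Mb and with the densest 1 Mb of every chromosome left out were chosen after the result was seen. A peak began at the first base of all 6 nuclear chromosomes in all 3 lists. The left-end scores ran from 8.20 on chromosome IV to 57.97 on I in the series-wide list, from 775 to 3100 in replicate 1 and from 141 to 480 in replicate 2. C. elegans chromosomes end in telomere repeats. Without the input samples, signal at these first bases cannot be assigned to MAU-2 binding. The last series-wide peak of all 6 nuclear chromosomes, with scores from 11.84 on II to 50.81 on I, was in neither replicate list and began beyond the last peak of both. Whether these peaks reach the right ends of the chromosomes was not tested, since the lengths were taken from the same list.

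A hypothesis for these missing last peaks is a signal too weak for the replicate lists. The other nuclear series-wide peaks of the same score range argue against it, since 339 of 339 (100%, 98.9 to 100) were found in at least 1 replicate list. With the 6 mitochondrial peaks in that range, of which 1 was found, the count was 340 of 345 (98.6%, 96.7 to 99.5). A difference between the peak callers stays open and untested, since the file columns name MACS for the replicate lists and MACS v2 for the series-wide list. Any other step that treated the 2 kinds of list differently also stays open, and no biological explanation was tested.

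Many of the peaks that no replicate list supports lay in 2 autosomal stretches, which held 42 of the 159 such nuclear peaks, 25 on IV from 6647002 to 6730864 and 17 on II from 9774551 to 9824204. Of the 159, 18 lay on X (11.3%, 6.85 to 17.3), compared with 194 of the 853 peaks found in at least 1 replicate list (22.7%, 20.0 to 25.7; Fisher's exact test, two-sided, p = 0.00092). Without these stretches the X share was 15.4% (9.38 to 23.2) against 22.9%, which did not pass (Fisher's exact p = 0.074). The share lying within 1000 bp of another peak or chain of peaks was 57.2% (49.2 to 65.0) against 38.9% (35.6 to 42.3) of the supported ones (Fisher's exact p = 2.4e-05), and 48.7% against 38.7% without the stretches (p = 0.044). These tests count peaks of one group as independent, which overstates their evidence. On X 33.5% (27.2 to 40.3) of peaks were grouped in this way and on autosomes 44.0% (40.5 to 47.5; Fisher's exact test, p = 0.0061). Of the 20 groups of 5 or more peaks, 3 were on X, and the median of their highest scores was 7.94. The group with the most peaks held 8, from 9428411 to 9435352 on V, and the widest of those with 7 ran from 10204049 to 10219277 on I. The density on X was 1.09 times that of the central 33.3% of the autosomes in the series-wide list (exact binomial p = 0.37), 1.40 times in replicate 1 (p = 7.7e-07) and 1.205 times in replicate 2 (p = 0.086). Leaving out the densest 100 kb of each chromosome gave 1.38 times in the series-wide list (exact binomial p = 0.0009). That removal, chosen by peak number, took autosome centres from 303 to 227 peaks and X from 212 to 202. Full lengths were kept, so the removal raises the ratio by construction, and its p-value is not evidence of a higher density on X.

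The higher X share did not come from X regions broken into several peaks at gaps of up to 1000 bp. It was 22.8% (19.8 to 26.03) after merging peaks within 1000 bp, against 17.7% of the genome length. Nor did it come from wide and chromosome-end peaks, without which it was 21.1% (18.5 to 23.8). Broad X regions broken at longer gaps stay open, since no longer merging distance was tried. Counted in covered bases, X held 20.4%, and the difference was not significant in the permutation test. A single dense region of X is not settled: without its densest 1 Mb, X held 19.1% (16.7 to 21.7) against 16.8% of the remaining length (exact binomial p = 0.061), an outcome set beforehand as going with such a region. That this removal lowers X alone by construction was weighed only after the value was seen, as was the removal of the densest 1 Mb of every chromosome, which left 22.9% (20.1 to 25.96) on X. No unusually dense 1 Mb of X was detected, as the densest held 23 peaks where the highest number at random was 21.3 on average (permutation p = 0.25, adjusted p of 0.0024 or less on each autosome), which does not exclude one. A higher density of MAU-2 sites on X stays open as a hypothesis, as does an unequal input signal.

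After merging peaks within 1000 bp, the median spacing of 86.5 kb fell inside the central 95% of random placement, 86.03 to 100.2 kb. Merging removes short gaps whatever their cause, so this value does not tell wide regions listed as several peaks from separate sites lying close together. Breaks of up to 1000 bp are not the whole of the close spacing, because 10.2% of the gaps were still under 5 kb after merging, where random placement gave 3.67% on average and 6.75% at most. Regions broken at longer gaps and separate sites stay open, since neither signal tracks nor gene positions were used.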
